A study of Mus musculus and Canis lupus familiaris with 12 samples.

How the data were processed

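RNA was taken from DLM8 (mouse) and Gracie (dog) osteosarcoma cells plated overnight and kept for 6 h with 50 nM omacetaxine (OMX) or without it, 3 libraries per group and 12 in all. Per the labels' protocols, RNA was purified on columns with DNase digestion, selected for poly(A), fragmented, copied to cDNA and made into libraries with the Universal Plus mRNA-Seq kit with NuQuant. The deposited values are whole-number counts per gene, tabulated for mouse and for dog with a column per library. Per the submitters' processing notes, STAR, featureCounts and Subread were used with the builds CanFam3.1, mm39 and GRCm39. Their versions, the strand setting, the treatment of read pairs and the rule for reads with several positions are not given in the sources used here. Even values made up most of the nonzero counts, as when both mates of a pair are counted apart, so a count is not an independent molecule and fits with halved counts were added after seeing the data. All columns were mapped to samples by the library names in the labels (0 were not).

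The mouse libraries held 9099313 to 11392715 counts and the dog libraries 2385102 to 3381831. Genes without a symbol held 29.2% to 33.1% of the mouse counts and 24.8% to 36.4% of the dog counts. They stayed in the tests under their Ensembl identifiers.

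Each line was fitted alone in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept (17109 of 78317 in DLM8 and 10423 of 30424 in Gracie), libraries were scaled by TMM, and OMX was compared with untreated by the quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested. A gene was called higher or lower at an adjusted p under 0.05, and genes over 2-fold were counted apart. Fold changes are on the log2 scale, OMX against untreated, and the standard error is the absolute log2 fold change divided by the square root of F. CPM use TMM-scaled library sizes and are given as mean and SD. MYC was also tested per line by an exact two-sided permutation test of CPM. Where a gene had 0 untreated counts the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a count ratio with an exact 95% interval, both also computed from halved counts.

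In all, 41 gene lists were fixed before the data were examined, as were the groups, tests, naming rule and most of the other settings tried. They cover the MYC network and its targets, immediate early genes, NF-kB and cytokines, interferon response, the integrated stress response, chaperones, p53, apoptosis, cell cycle, replication, mRNA decay and splicing, translation, ribosomes, metabolism, bone and matrix genes, signalling pathways, histones, zinc finger genes, and markers of other cell types. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 (36 lists in DLM8 and 34 in Gracie), with adjustment over the lists of a line. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members move one way on balance, and its mixed test whether they change in either direction, and neither compares a list with other genes.

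The lines were compared over 7566 genes with the same symbol regardless of case, 1 per symbol in each table, that passed the filter in both. The interaction of line and treatment was tested with edgeR, with library sizes and TMM factors computed within each line. Both comparisons share no control libraries.

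The naming rule took, per line, MYC and the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3, no overlap of the groups and a symbol that is not of the Gm, Rik or LOC kind. It took 3 members with the smallest p in the direction of each called list, 2 members with the smallest p of every other list, the 6 largest positive and 6 largest negative interactions with a mean log2 CPM of at least 3 in both lines, and 5 shared rises and 5 shared falls with the largest sum. Examples may be left out where a list repeats genes already named. Genes named outside this rule are marked as picked after their values were seen. Values of a few genes are not reported here.

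The mouse annotation used here was GENCODE M21, of another build than the table, so no coordinates are given. It served for gene types, exon lengths, 3' UTRs and which genes overlap on opposite strands (face each other), and 51536 of 78317 mouse genes, with 63.2% of the counts, matched it by identifier. Dog gene positions were not used here, and a dog gene is said to face a gene where its mouse counterpart does.

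The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For DLM8 (15769 genes) 45% and 78% were recovered with 5 false calls, for Gracie (9794 genes) 15% and 83% with 4, and for the interaction (7134 genes) 8% and 58% with 3. The list test called the 1 planted list and 0 of 20 unchanged lists in each line, and the motif model (10354 genes) returned 0.28 for a planted 0.3 and -0.016 for a planted 0. Simulated genes were drawn independently of each other, so the list result does not test for false calls among correlated genes.

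Other settings tried were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's test against a 1.2-fold change, the replicate number as a block, and leaving out each library. Those chosen after seeing the data were halved counts, Gracie without the 2 genes with the most counts, and DLM8 genes and lists limited to genes facing no annotated gene. Files were read with the data.table package (version 1.17.8).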

Results

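Gene expression was measured by sequencing of poly(A)-selected RNA in 2 osteosarcoma cell lines, DLM8 from mouse and Gracie from dog, after 6 h in 50 nM omacetaxine (OMX) and in untreated cells. Omacetaxine is a plant alkaloid that blocks the elongation step of protein synthesis at the ribosome. Each line had 3 OMX and 3 untreated libraries, 12 in all. The treatment protocol names DMSO as the control, while the sample labels call the control cells untreated. The mouse table held 78317 genes and 9099313 to 11392715 counts per library, and the dog table held 30424 genes and 2385102 to 3381831 counts per library. The dog libraries were thus counted at lower depth, and the common biological coefficient of variation was 0.296 in Gracie and 0.246 in DLM8. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. With 3 libraries against 3, an exact two-sided permutation test cannot give a p below 0.1. Intervals and lower bounds below cover counting error only and take each count as independent, which makes them too narrow or too high where both mates of a pair were counted apart. With halved counts, a setting added after seeing the data, the 10 lower bounds were 0.503 to 0.512 times those given, and each interval is also given so.

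Where genes overlapped on opposite strands, the counts lay mostly in the non-coding row. Among 881 pairs in DLM8 of a protein-coding gene and a non-coding gene that overlap on opposite strands and overlap no other gene so, the non-coding row held more counts in 757 (85.9%), with a median ratio of 6.32. The row of mt-Nd6, the only protein-coding gene of the mitochondrial light strand, held 49.9 to 94.1 times the median of the other 12 mitochondrial protein-coding rows in the 6 DLM8 libraries. Of 78 ribosomal protein genes, 4 were among the 1000 rows with the most counts. In the 507 pairs whose facing row held over 5 times the counts of the protein-coding row, the log2 fold changes of both rows correlated across genes (Pearson r = 0.893, genes not being independent replicates), and 144 of the 145 pairs called in both rows had the same direction. A gene's values below are those of its own row, so its level cannot be read as its mRNA level. Whether its fold change is that of its mRNA was not tested, also for genes that face no annotated gene. Genes with an opposite-strand neighbour are the most uncertain. Of the 117 DLM8 genes chosen for naming, 35 face an annotated gene, and for Gracie the mouse counterparts of 26 of 106 do, since dog gene positions were not used here.

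**Figure D1:**
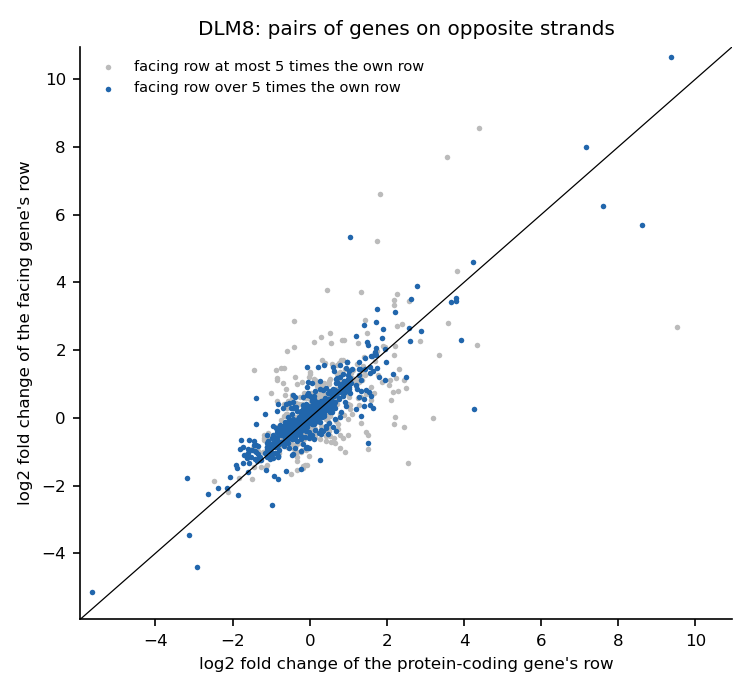
Log2 fold changes (OMX against untreated, DLM8) of 881 protein-coding rows on the x axis and of the non-coding row facing each on the y axis, each point a pair and the line marking equal change. Blue points, the 507 pairs whose facing row held over 5 times the counts of the protein-coding row, follow the line with Pearson r = 0.893.

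The series title states a reduction of c-Myc, without saying whether of RNA or protein, and the first comparison asked how the MYC row, of the proto-oncogene transcription factor, differed after OMX. In DLM8 the Myc row (ENSMUSG00000022346) rose 2.42-fold, from 41.0 ± 8.99 to 99.3 ± 17.6 CPM (counts scaled to library size, SD, n = 3). Its log2 fold change was 1.27 (SE 0.19, adjusted p = 0.000351 by edgeR's quasi-likelihood test), and all 3 OMX libraries lay above the untreated ones (exact permutation p = 0.1, the smallest this design allows). In Gracie the MYC row (ENSCAFG00000001086) held 119 ± 36.4 CPM untreated and 171 ± 51.8 CPM with OMX (SD, n = 3). Its log2 fold change of 0.52 (SE 0.27) was within the spread between libraries (adjusted p = 0.19, exact permutation p = 0.3). The difference between both responses was 0.75 (SE 0.37, adjusted p = 0.204), so the lines were not shown to differ. No annotated gene faces Myc in the mouse annotation used here, but the limit of strand stated above holds for the Myc row. It may hold for the MYC row of Gracie too, as the dog table was not tested for it.

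**Figure D2:**
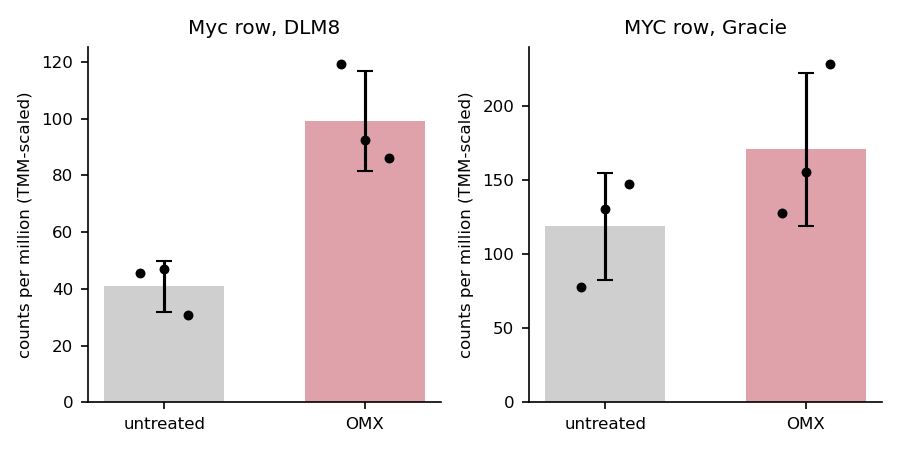
TMM-scaled CPM in the Myc row of DLM8 (left) and the MYC row of Gracie (right), untreated and after OMX. Points are libraries, bars means and error bars SD (n = 3): means of 41.0 and 99.3 CPM in DLM8, and of 119 and 171 CPM in Gracie, where the groups overlap.

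Genes around MYC moved both ways. In the network of MYC partners and antagonists 3 of 11 measured DLM8 genes were higher (Myc, Mlxip and Mxd1), 2 were lower (Mxd3 and Mxi1) and 6 were not called, with 3 and 3 adjusted over the list alone. The list was not called (adjusted p = 0.963), its median was 0.29 and its mean 0.22, while fry, a test of a shared direction, pointed down (adjusted p = 0.734). Mxd3, which encodes a MYC antagonist, fell by 1.33 on the log2 scale (SE 0.11, adjusted p = 3.24e-06), and Prelid1, the gene facing it, fell by 0.49. The Prelid1 row held 0.958 times the counts of the Mxd3 row, so which gene's reads the Mxd3 row holds is uncertain. Of 61 measured MYC target genes in DLM8, 24 were lower, 1 (Rrp9) was higher and 36 were not called, with 24 lower and 1 higher adjusted over the list alone. This list was called lower (median -0.40, adjusted p = 9.81e-05), a call lost at adjusted p = 0.356 with an estimated correlation. Ldha, the lactate dehydrogenase A gene, fell by 1.72 (SE 0.14), the mitochondrial chaperonin gene Hspd1 by 1.59 (SE 0.13) and Tmem97 by 1.66 (SE 0.19). In Gracie 5 of 52 MYC target genes were lower (HK2, CCND2, CDK4, DCTPP1 and SLC19A1), 4 were higher (PPRC1, NOP16, PPAN and MAP3K6) and 43 were not called, with 5 and 4 adjusted over the list alone. That list was not called (median -0.19, adjusted p = 0.0761). Of the 8 MYC network genes measured in Gracie, MGA was higher, MAX lower and 6 not called, with 1 higher and 2 lower adjusted over the list alone (list adjusted p = 0.68). The call of MGA was lost without untreated replicate 2 (adjusted p = 0.0585), OMX replicate 2 (0.0563) or OMX replicate 3 (0.0626), and that of MAX without any 1 library but OMX replicate 1 (adjusted p from 0.0587 to 0.148). The MYC target list of Gracie was called lower without untreated replicate 1 (adjusted p = 0.0199) or OMX replicate 3 (0.00576). The members named without a value in this and the following paragraphs were picked after their values were seen, because few members of their list were called.

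The comparison of OMX with untreated DLM8 cells asked which genes respond to the compound. Higher rows were 29 of 31 NF-kB target and cytokine genes, 28 of 42 immediate early genes and 20 of 28 interferon-response genes. Lower rows were 55 of 78 ribosomal protein genes and 18 of 26 chaperone and unfolded protein response genes of the endoplasmic reticulum. So were 14 of 24 cholesterol synthesis genes and 18 of 39 mitosis genes. Each of these 7 lists was called by camera with its preset correlation, and with an estimated correlation the NF-kB call held and the others were lost (adjusted p = 0.0539 to 0.294 with an estimated correlation). Egr1, an immediate early transcription factor gene, rose from 0.379 ± 0.352 to 119 ± 27.6 CPM (SD, n = 3), a log2 fold change of 8.34 (SE 0.42, adjusted p = 7.18e-08). The chemokine gene Cxcl1 rose from 11.3 ± 1.18 to 547 ± 102 CPM (log2 fold change 5.59, SE 0.18, adjusted p = 6.64e-09). Trib3, a pseudokinase gene induced by ATF4 in the integrated stress response, fell from 14.4 ± 0.525 to 0.846 ± 0.413 CPM (log2 fold change -4.05, SE 0.36, adjusted p = 6.03e-06). Of 17109 genes tested with edgeR's quasi-likelihood test, 3311 were higher and 2726 lower at an adjusted p under 0.05, 2384 and 1288 of them over 2-fold. Both groups did not overlap in 5899 of the called genes, and in 49.0% of all tested genes, where chance gives 10%. Scaling by library size alone raised the share of higher calls from 54.8% to 66.6% (3977 higher and 1991 lower) and moved the median of all genes by 0.14, so changes are relative to the median gene. Upper-quartile scaling gave 3077 higher and 3121 lower, and genes facing no annotated gene 1107 higher and 1242 lower, so which direction held more calls depended on the scaling and on the genes tested.

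Of the largest rises by the naming rule, Neurl3, a ubiquitin ligase gene, reached a log2 fold change of 7.73 (SE 0.30) and Icam1, the gene of an adhesion molecule for leukocytes, 7.65 (SE 0.35). The row facing Icam1, Gm47079, held 20.3 times its counts and rose by 5.53 (SE 0.27). Dll4, which encodes a Notch ligand, rose by 7.17 (SE 0.43) and its facing row Gm14207 by 7.99 (SE 0.23). Rises followed for Erdr1y (6.78, SE 1.19), the chemokine gene Ccl2 (6.71, SE 0.42), the NF-kB inhibitor gene Nfkbie (5.93, SE 0.23) and the stress-response gene Gadd45b (5.81, SE 0.21). Among genes with a mean log2 CPM of at least 3, the largest falls were those of Lrp2bp (-3.68, SE 0.27), Fbxl13 (-3.57, SE 0.35), the secreted Wnt modulator gene Sfrp2 (-3.12, SE 0.24), the lipoprotein receptor gene Vldlr (-3.04, SE 0.32), the glucose transporter gene Slc2a1 (-2.92, SE 0.38), the hexokinase gene Hk2 (-2.87, SE 0.37), Tmem119 (-2.74, SE 0.31) and the transcription factor gene Hand1 (-2.73, SE 0.17). The rows facing Sfrp2 and Slc2a1 held 11.6 and 5.79 times their counts and fell by 3.47 (SE 0.16) and 4.41 (SE 0.20). Lrp2bp faces Ankrd37, whose row held 0.0787 times its counts and was not called (-0.38, SE 0.56). Fbxl13 faces Lrrc17, whose row held 0.0923 times its counts. With counting on the opposite strand, a candidate explanation weighed below, the Lrp2bp and Fbxl13 rows would hold reads of Ankrd37 and Lrrc17. Which gene of each pair fell is therefore uncertain.

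Of 31 measured members of the NF-kB and cytokine list in DLM8 29 were higher, 0 lower and 2 not called (Nfkbib and Il1a), the same 29 and 0 adjusted over the list alone. Its median log2 fold change was 3.25, also with 4 genes at 0 counts set to their bound, and it was the 1 called list of the line to keep its call with an estimated correlation (adjusted p = 0.0162). Csf2, which encodes the growth factor GM-CSF, had 0 counts untreated and 80 with OMX, at least 25.0-fold higher (floor of 3 counts over the group). The filter kept 31 of the 38 list genes with a row. Genes at 0 counts untreated, such as Csf2, passed it only by their counts with OMX. The count of higher genes is thus partly set by the filter, as in other lists of either line with such genes. Of 42 immediate early genes 28 were higher, 1 was lower (Ccn1) and 13 were not called, with 28 and 1 adjusted over the list alone. The list was called higher (median 1.23, adjusted p = 4.7e-09), with adjusted p = 0.142 with an estimated correlation. Klf10, a zinc finger repressor gene induced by TGF-beta, rose by 4.47 (SE 0.26). Of 28 interferon-response genes 20 were higher, 0 lower and 8 not called, with 22 higher adjusted over the list alone (median 1.58, adjusted p = 1.37e-06, and adjusted p = 0.161 with an estimated correlation). Rigi, a sensor of viral RNA, rose by 2.86 (SE 0.23), and Mx2, an antiviral GTPase gene, went from 2 to 257 counts, a ratio of 121 (95% interval 33.1 to 1002, or 21.5 to 4859 with halved counts). Oasl1 rose by 3.58 (SE 0.44) and faces Gm13822, which rose by 2.79 (SE 0.47).

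Of the further lists called higher in DLM8, YAP and TEAD target genes had 12 of 20 higher, 1 lower (Ccn1) and 7 not called, with 13 and 1 adjusted over the list alone (median 0.76, adjusted p = 0.000785, and adjusted p = 0.142 with an estimated correlation). Ajuba, a LIM protein gene, rose by 2.55 (SE 0.26). Of 19 genes of feedback and output of MAP kinase signalling 9 were higher, 1 was lower (Dusp7) and 9 were not called, also 9 and 1 adjusted over the list alone. That list's call (median 1.49, adjusted p = 0.026) was lost at adjusted p = 0.16 with an estimated correlation and without untreated replicate 1 (0.117) or 2 (0.0504), OMX replicate 1 (0.116) or OMX replicate 3 (0.0766). Its median was 0.76 without the first of these, 0.50 without OMX replicate 1 and 0.28 without OMX replicate 3. Lif, a cytokine gene of the list, rose by 4.36 (SE 0.23). Replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, had 4 of 6 higher (H1f2, H2bc4, H2ac21 and H4c9), 0 lower and 2 not called, with 5 higher adjusted over the list alone. These 6 were what the filter kept of 68 histone genes. H2ac21 (0 counts untreated), H2bc4 (2) and H1f2 (8) passed it only by their counts with OMX. The count of higher genes, the list's median and its p are thus partly set by the filter. The histone median was 4.36, or 3.84 with genes at 0 counts set to their bound and 3.36 with that bound from halved counts (adjusted p = 0.000379, and adjusted p = 0.0872 with an estimated correlation). H1f2 went from 8 to 348 counts, a log2 fold change of 5.30 (SE 0.61), H2bc4 from 2 to 130 counts, a ratio of 61.0 (95% interval 16.6 to 509, or 10.7 to 2467 with halved counts), and H2ac21 from 0 to 61, at least 19.1-fold higher. Numbered zinc finger genes had 67 of 254 higher, 9 lower and 178 not called, with 60 and 8 adjusted over the list alone (median 0.67, adjusted p = 1.37e-05, and adjusted p = 0.0759 with an estimated correlation). Zfp119b rose by 3.45 (SE 0.30). Zfp36, in that list by its name, encodes an mRNA decay factor, and it rose by 2.70 (SE 0.29) while its facing row Gm44710, with 8.20 times its counts, had a log2 fold change of 0.02 (SE 0.15).

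In DLM8 16 lists were called lower. Of 78 cytosolic ribosomal protein genes 55 were lower, 0 higher and 23 not called, with 60 lower adjusted over the list alone. The median was -0.60 (adjusted p = 6.03e-11), and the call was lost at adjusted p = 0.294 with an estimated correlation. Rpsa fell by 0.72 (SE 0.10) and Rps4x by 0.88 (SE 0.13). Translation factor genes had 21 of 46 lower, 0 higher and 25 not called, with 25 lower and 1 higher adjusted over the list alone (median -0.61, adjusted p = 2.5e-06, and adjusted p = 0.302 with an estimated correlation). The poly(A)-binding protein gene Pabpc1 fell by 1.28 (SE 0.13) and the elongation factor gene Eef1a1 by 0.85 (SE 0.12). Chaperone and unfolded protein response genes of the endoplasmic reticulum had 18 of 26 lower, 2 higher (Derl3 and Ern1) and 6 not called. Adjusted over the list alone, 19 were lower and 2 higher. The list's median was -1.37 (adjusted p = 7.71e-08 by camera, and adjusted p = 0.0539 with an estimated correlation). Calreticulin (Calr) fell by 1.61 (SE 0.13), Pdia4, a protein disulfide isomerase gene, by 2.17 (SE 0.18) and Hsp90b1 by 1.97 (SE 0.16). Cytosolic heat shock genes had 9 of 24 lower, 0 higher and 15 not called, with 10 lower adjusted over the list alone (median -0.38, adjusted p = 0.00256, and adjusted p = 0.145 with an estimated correlation). Hspa8 fell by 1.26 (SE 0.13) and Hsph1 by 1.85 (SE 0.18). Proteasome genes had 16 of 31 lower, 0 higher and 15 not called, with 18 lower adjusted over the list alone (median -0.62, adjusted p = 2.32e-06, and adjusted p = 0.0578 with an estimated correlation). Psmd2 fell by 1.09 (SE 0.15).

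Genes of the integrated stress response had 18 of 34 lower, 4 higher (Cebpb, Slc3a2, Gdf15 and Ppp1r15a) and 12 not called, the same 18 and 4 adjusted over the list alone (median -0.77, adjusted p = 0.000435, and adjusted p = 0.26 with an estimated correlation). Slc7a5, a transporter gene for large neutral amino acids, fell by 1.93 (SE 0.20). Cholesterol synthesis genes had 14 of 24 lower, 0 higher and 10 not called, also 14 adjusted over the list alone (median -1.01, adjusted p = 4.63e-07, and adjusted p = 0.0763 with an estimated correlation). Sqle, the squalene epoxidase gene, fell by 1.66 (SE 0.20). Glycolysis and hypoxia genes had 20 of 32 lower, 2 higher (Eno2 and Pfkfb3) and 10 not called, with 21 and 2 adjusted over the list alone (median -0.98, adjusted p = 7.1e-07, and adjusted p = 0.26 with an estimated correlation). Pgam1 fell by 2.12 (SE 0.22). Nuclear genes of oxidative phosphorylation had 10 of 36 lower, 1 higher and 25 not called, with 9 and 1 adjusted over the list alone (median -0.50, adjusted p = 0.000264, and adjusted p = 0.0759 with an estimated correlation). Cyc1, of cytochrome c1, fell by 0.87 (SE 0.20). Of 7 mitochondrially encoded genes 5 were lower and 2 not called, with 7 lower adjusted over the list alone (median -0.64, adjusted p = 0.0102, and adjusted p = 0.431 with an estimated correlation). These were mt-Nd1 (-1.06, SE 0.21), mt-Nd6 (-0.64, SE 0.14), mt-Nd4, mt-Cytb and mt-Co1, of which mt-Nd4 lost its call without OMX replicate 2 (adjusted p = 0.0549). Antioxidant genes of the NRF2 pathway had 8 of 18 lower, 3 higher (Osgin1, Abcc1 and Nfe2l2) and 7 not called, the same adjusted over the list alone (median -0.70, adjusted p = 0.0448, and adjusted p = 0.442 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.0545), OMX replicate 2 (0.0741) or OMX replicate 3 (0.0833), among genes facing no annotated gene (0.281), and by fry (0.0525). Pgd fell by 1.30 (SE 0.17).

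Genes of mitosis had 18 of 39 lower, 0 higher and 21 not called, also 18 adjusted over the list alone (median -0.76, adjusted p = 4.63e-07, and adjusted p = 0.142 with an estimated correlation). Plk1, a mitotic kinase gene, fell by 1.89 (SE 0.25) with its facing row Gm44985 at -1.49 (SE 0.18), and the cyclin gene Ccnb1 fell by 1.59 (SE 0.25). DNA replication and G1/S genes had 10 of 42 lower, 2 higher (Gins2 among them) and 30 not called, with 10 and 1 adjusted over the list alone (median -0.32, adjusted p = 0.0273, and adjusted p = 0.431 with an estimated correlation), a call lost without OMX replicate 1 (adjusted p = 0.0700, median -0.12). The helicase genes Mcm2 and Mcm3 fell by 1.07 (SE 0.17) and 1.00 (SE 0.18). Osteoblast genes had 6 of 14 lower, 1 higher (Bmp4) and 7 not called, with 10 and 1 adjusted over the list alone (median -0.75, adjusted p = 0.00079, and adjusted p = 0.0872 with an estimated correlation). Osteopontin (Spp1) fell by 2.01 (SE 0.18) and alkaline phosphatase (Alpl) by 1.56 (SE 0.17). Extracellular matrix genes had 12 of 29 lower, 3 higher (Mmp9 and Col4a2 among them) and 14 not called, the same adjusted over the list alone (median -0.47, or -0.72 without untreated replicate 3, adjusted p = 0.00668, and adjusted p = 0.431 with an estimated correlation). The collagen gene Col1a2 fell from 894 ± 56.9 to 312 ± 66.6 CPM, and Serpinh1, a collagen chaperone gene, fell by 1.98 (SE 0.17).

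Of the 36 lists tested in DLM8, 13 were not called (adjusted p from 0.121 to 0.963), the MYC network above among them. For p53 targets 7 of 27 were higher and 2 lower (Ei24 and Ccng1), for snoRNA host genes 6 of 15 higher and 2 lower (Snhg4 and Snhg14), and for mRNA decay factors 6 of 25 higher and 3 lower (Khsrp, Cnot7 and Cnot6), each with the same counts adjusted over the list alone. Plk2, a p53 target and kinase gene, rose by 4.64 (SE 0.40), Snhg15 by 3.27 (SE 0.42) and Zc3h12a, the gene of an endonuclease that cuts cytokine mRNAs, by 2.12 (SE 0.28). BCL2 family genes had 3 of 11 higher (Bbc3, Bad and Bcl2l1) and 2 lower (Bak1 and Bok), and caspases, their inhibitors and death receptors 5 of 20 higher (Birc3, Fas, Casp4, Birc2 and Ripk1) and 2 lower (Cycs and Tnfrsf1a), the same adjusted over the list alone. The median of the latter was -0.11, its mean 0.51 and its test pointed up (adjusted p = 0.948). Cyclins, kinases and their inhibitors had 3 of 27 higher (Ccnl1, Cdk6 and Ccnt1) and 5 lower (Cdk1, Ccna2, Cdkn2c, Ccnd3 and Cdk2), growth factor receptors 5 of 17 higher (Epha2, Egfr, Flt1, Axl and Fgfr3) and 2 lower (Igf2r and Ddr2), and TGF-beta and BMP genes 4 of 20 higher (Skil, Smad7, Snai1 and Snai2) and 6 lower, the same adjusted over the list alone. In the TGF-beta and BMP list the median was 0.02, the mean -0.06 and the test pointed down (adjusted p = 0.751). Wnt and Notch targets had 3 of 14 higher (Heyl, Axin2 and Nkd1) and 3 lower (Sfrp2, Dkk3 and Tcf7), with fry pointing down against a mean of 0.01. SR proteins and splicing factors had 3 of 27 higher (Son, Clk4 and Tra2a) and 3 lower (Srsf9, Ptbp1 and Hnrnpa1), RNA polymerase I and ribosome biogenesis genes 2 of 40 higher (Taf1a and Taf1d) and 5 lower (Lyar, Fbl, Dkc1, Nop10 and Nhp2), and nonsense-mediated decay factors 1 of 10 lower (Upf1), again the same adjusted over the list alone. The RNA polymerase I list was called lower without untreated replicate 3 (adjusted p = 0.0268) or OMX replicate 1 (0.0239), and the p53 list higher among genes facing no annotated gene (0.0221). Fry called the p53 (adjusted p = 0.0212), BCL2 family (0.0197) and snoRNA host lists (0.0101) higher and the cyclin list lower (0.0197). Marker lists of other cell types had too few measured genes to test. Of these, the endothelial cadherin gene Cdh5 went from 0 to 99 counts (at least 31.0-fold higher) and the epithelial factor gene Elf3 from 0 to 160 (at least 50.1-fold higher). Muscle titin (Ttn) was higher by 1.43 (SE 0.39), cartilage collagen Col2a1 lower by -1.46 (SE 0.19), and the 3 leukocyte markers measured were not called. Adjusted over the list alone, Vwf and Sox9 were also higher and Ctsk lower. These markers, all the called ones included, were picked for the text after their values were seen.

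In Gracie the higher rows with OMX were 24 of 37 immediate early genes and 17 of 28 NF-kB and cytokine genes. Histone genes kept by the filter had 10 of 10 higher and numbered zinc finger genes 58 of 179. Lower rows were 9 of 25 chaperone and unfolded protein response genes of the endoplasmic reticulum. So were 8 of 37 DNA replication genes and 9 of 28 glycolysis and hypoxia genes. Of these list calls the zinc finger one held with an estimated correlation and the others were lost (adjusted p = 0.133 to 0.668 with an estimated correlation). GADD45B, a stress-response gene, rose from 14.1 ± 1.36 to 553 ± 20.8 CPM (SD, n = 3), a log2 fold change of 5.29 (SE 0.22, adjusted p = 1.3e-08). WNT7B, which encodes a Wnt ligand, went from 0 to 260 counts and CYP1A2, a cytochrome P450 gene, from 0 to 182, at least 76.1-fold and 53.3-fold higher (floor of 3 counts over the group). PAMR1 fell from 1499 ± 189 to 127 ± 35.5 CPM (log2 fold change -3.56, SE 0.24, adjusted p = 9.11e-07). Of 10423 genes tested with edgeR's quasi-likelihood test, 1308 were higher and 840 lower at an adjusted p under 0.05, 1053 and 541 of them over 2-fold. Both groups did not overlap in 2110 of the called genes and in 39.7% of all tested genes, where chance gives 10%. Without OMX replicate 2 the counts were 827 higher and 395 lower (358 lower over 2-fold), and the lower count was 495 without untreated replicate 2 and 553 without OMX replicate 3. With library size alone 1084 were higher and 1204 lower, so the share of higher calls went from 60.9% to 47.4%, and the median of all genes moved by -0.13. In this line 2 genes without a symbol (ENSCAFG00000044432 and ENSCAFG00000018897) held 3.99% to 4.32% of the counts of untreated libraries together and 13.3% to 17.4% of those with OMX.

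Of the other large rises, the histone gene H2AC17 went from 0 to 160 counts (at least 46.8-fold), SDK2 from 0 to 147 (at least 43.0-fold) and the kinase gene MAP3K9 from 0 to 141 (at least 41.3-fold). The nitric oxide synthase gene NOS3 went from 2 to 381 counts, a ratio of 167 (95% interval 46.0 to 1386, or 29.9 to 6700 with halved counts), NEURL3 from 2 to 311, a ratio of 137 (37.5 to 1132, or 24.4 to 5479), and the arrestin-domain gene ARRDC4 from 2 to 255, a ratio of 112 (30.7 to 929, or 19.9 to 4502). Falls were led by LGR4, a receptor gene for R-spondins (-4.66, SE 0.60), FAM20C, a secretory kinase gene of mineralised tissue (-3.74, SE 0.42), ANGPTL2 (-3.72, SE 0.27), FSTL1 (-3.45, SE 0.52), the microRNA-processing gene DICER1 (-3.34, SE 0.34), the transcription factor gene E2F8 (-3.19, SE 0.58) and ST8SIA1 (-3.14, SE 0.69).

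Of 37 immediate early genes measured in Gracie 24 were higher, 0 lower and 13 not called, with 27 higher adjusted over the list alone (median 1.74, adjusted p = 7.18e-11, and adjusted p = 0.144 with an estimated correlation). KLF10 rose by 3.73 (SE 0.27) and KLF6 by 3.22 (SE 0.21). NF-kB and cytokine genes had 17 of 28 higher, 1 lower (TNF) and 10 not called, with 19 and 1 adjusted over the list alone (median 1.56, adjusted p = 2.5e-07, and adjusted p = 0.171 with an estimated correlation). IRF1 rose by 4.32 (SE 0.27), the apoptosis inhibitor gene BIRC3 by 3.86 (SE 0.25) and RELB, of the NF-kB family, by 3.62 (SE 0.25). Of 53 replication-dependent histone genes the filter kept 10. Those with 0 or few untreated counts, such as H2AC17 at 0, passed it only by their counts with OMX. The count of higher genes, the list's median and its p are thus partly set by the filter. All 10 were higher, also 10 adjusted over the list alone. Their median was 4.82, or 4.42 with genes at 0 counts set to their bound and 4.32 with that bound from halved counts (adjusted p = 3.17e-09, and adjusted p = 0.133 with an estimated correlation), and H2AC9 went from 58 to 2094 counts (log2 fold change 4.95, SE 0.37). Numbered zinc finger genes had 58 of 179 higher, 3 lower (ZNF263, ZNF395 and ZNF706) and 118 not called, with 67 and 7 adjusted over the list alone. This was the 1 list of the line whose call held with an estimated correlation (median 0.86, adjusted p = 2.11e-09, and adjusted p = 0.0185 with an estimated correlation). ZNF697 rose by 2.01 (SE 0.17) and ZNF608 by 2.68 (SE 0.35).

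Genes of TGF-beta and BMP signalling had 8 of 17 higher, 0 lower and 9 not called, with 9 higher and 1 lower adjusted over the list alone (median 0.84, or 1.31 without untreated replicate 1, adjusted p = 0.00751, and adjusted p = 0.432 with an estimated correlation). SMURF1, a ubiquitin ligase gene of the pathway, rose by 2.70 (SE 0.32), and the BMP target genes ID3 and ID1 by 2.28 (SE 0.30) and 1.51 (SE 0.21). Of 20 p53 targets 6 were higher, 1 was lower (EI24) and 13 were not called, with 7 and 1 adjusted over the list alone (median 0.80, adjusted p = 0.0356, and adjusted p = 0.299 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.0534), 2 (0.144) or 3 (0.0670) and without OMX replicate 1 (0.150) or 2 (0.0947). The median was 0.48 without untreated replicate 1 and 0.45, 0.36 and 0.32 without OMX replicates 1, 2 and 3. CDKN1A, the gene of the cell cycle inhibitor p21, rose by 1.88 (SE 0.26) and PLK2 by 3.61 (SE 0.39). BCL2 family genes had 4 of 10 higher (MCL1, BCL2A1, PMAIP1 and BBC3), 1 lower (BAK1) and 5 not called, with 5 and 1 adjusted over the list alone (median 1.08, adjusted p = 0.0347, and adjusted p = 0.384 with an estimated correlation), a call lost without OMX replicate 1 (adjusted p = 0.122) or 2 (0.145). BCL2A1 lost its own call without OMX replicate 2 (adjusted p = 0.0501). MCL1, an anti-apoptotic gene, rose by 1.37 (SE 0.23), and PMAIP1, which encodes the pro-apoptotic NOXA, went from 2 to 59 counts, a ratio of 25.9 (95% interval 6.86 to 219, or 4.41 to 1081 with halved counts). Both untreated counts of PMAIP1 were in replicate 2, and without it the fitted log2 fold change went from 4.53 to 7.28 against untreated counts of 0, which is no bound.

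Chaperone and unfolded protein response genes of the endoplasmic reticulum had 9 of 25 lower in Gracie, 0 higher and 16 not called. Adjusted over the list alone, 10 were lower. The list's median was -0.61 (adjusted p = 8.97e-05 by camera, and adjusted p = 0.144 with an estimated correlation). HYOU1 fell by 1.93 (SE 0.27) and calnexin (CANX) by 1.34 (SE 0.19). Ribosomal protein genes had 3 of 57 lower (RPL7, RPL26 and RPL14), 0 higher and 54 not called, with 0 adjusted over the list alone (median -0.35, adjusted p = 8.05e-05, and adjusted p = 0.668 with an estimated correlation). RPL7 (-0.72, SE 0.19) lost its call without untreated replicate 2, OMX replicate 1 or OMX replicate 2 (adjusted p from 0.0505 to 0.0604), RPL26 (-0.67, SE 0.19) without these or OMX replicate 3 (0.0537 to 0.0785), and RPL14 (-0.61, SE 0.19) without any 1 library but untreated replicate 1 (0.0518 to 0.147). DNA replication and G1/S genes had 8 of 37 lower, 2 higher (GINS2 and GINS3) and 27 not called, with 10 and 2 adjusted over the list alone (median -0.49, adjusted p = 0.00142, and adjusted p = 0.609 with an estimated correlation). UHRF1, which couples DNA methylation to replication, fell by 1.74 (SE 0.28). Glycolysis and hypoxia genes had 9 of 28 lower, 4 higher (SLC16A3, PFKFB3, PFKFB4 and NDRG1) and 15 not called, with 11 and 5 adjusted over the list alone (median -0.62, adjusted p = 0.0118, and adjusted p = 0.668 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.0596) or OMX replicate 3 (0.0902). SLC2A1 fell by 2.28 (SE 0.24) and HK2 by 1.84 (SE 0.28). Extracellular matrix genes had 7 of 28 lower, 3 higher (THBS1 and COL12A1 among them) and 18 not called, with 9 and 3 adjusted over the list alone (median -0.64, adjusted p = 0.0315, and adjusted p = 0.668 with an estimated correlation). This call was lost without untreated replicate 1 (median -0.02, adjusted p = 0.410) or 2 (0.0696) and without OMX replicate 2 (0.0852) or 3 (median -0.36, 0.141). MMP14, a membrane collagenase gene, fell from 488 ± 145 to 70.0 ± 8.97 CPM (log2 fold change -2.80, SE 0.24). Nuclear genes of oxidative phosphorylation had 3 of 28 lower (ATP5F1C and ATP5F1B among them), 1 higher (UQCRC1) and 24 not called, the same adjusted over the list alone (median -0.27, adjusted p = 0.0374, and adjusted p = 0.668 with an estimated correlation). That list lost its call without untreated replicate 2 (adjusted p = 0.0696) or 3 (0.0843) or OMX replicate 1 (0.150), and its median was -0.44 without untreated replicate 1 and -0.45 without OMX replicate 3. ATP5F1B lost its call without untreated replicate 2 (0.0579) or OMX replicate 2 (0.0692). ATP5F1C, of ATP synthase, fell by 1.15 (SE 0.23). Fry did not call the Gracie lists of ribosomal protein (adjusted p = 0.0757), DNA replication (0.0896), oxidative phosphorylation (0.141), glycolysis (0.186) and extracellular matrix genes (0.259).

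Of the 34 lists tested in Gracie, 21 were not called (adjusted p from 0.0761 to 0.958), both MYC lists above among them. Integrated stress response genes had 5 of 28 lower (SLC7A5, PSAT1, DDIT4, SLC7A1 and SHMT2) and 2 higher, with 6 and 2 adjusted over the list alone. Those higher were ATF4, the transcription factor gene of that response, which rose by 1.84 (SE 0.20), and PPP1R15A, a phosphatase subunit gene, which rose by 2.30 (SE 0.29). Without untreated replicate 1 this list (adjusted p = 0.0483), the heat shock list (0.0368), the NRF2 list (0.0483) and the proteasome list (0.0368) were called lower, and without OMX replicate 3 the stress response list was (0.0430). Heat shock genes had 3 of 21 lower (HSPA8, HSPA4L and AHSA1) and 1 higher (BAG3), translation factors 3 of 39 lower (EIF4EBP2, PABPC1 and EEF1A1) and 1 higher (EIF3G), and proteasome genes 1 of 26 higher (PSMC1), each the same adjusted over the list alone. EIF3G, of an initiation factor subunit, rose by 2.01 (SE 0.21), and EIF4EBP2, of a repressor of cap-dependent translation, fell by 2.03 (SE 0.31).

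Mitosis genes had 3 of 36 lower in Gracie (FOXM1, TOP2A and KIF23) and 1 higher (AURKA), with 2 and 1 adjusted over the list alone. Cyclins, kinases and their inhibitors had 5 of 25 lower (CCND1, CCND2, CDC25B, CDK4 and CDC25A) and 3 higher (CDKN1A, CCNL1 and CDK6), the same adjusted over the list alone, and the cyclin D1 gene CCND1 fell by 1.77 (SE 0.25). Cholesterol synthesis genes had 2 of 22 higher (MVD and FDFT1) and 2 lower (SQLE among them), with 4 and 3 adjusted over the list alone. NRF2 genes had 4 of 19 lower (PRDX1, FTL, FTH1 and ABCC1) and 3 higher (OSGIN1, NFE2L2 and SRXN1), with 7 and 3 adjusted over the list alone, and fry called this list lower (adjusted p = 0.00629). Of 6 osteoblast genes SP7, which encodes osterix, rose by 2.35 (SE 0.35) and SPARC, which encodes osteonectin, fell by 2.15 (SE 0.37), with 1 higher and 2 lower adjusted over the list alone. The median of that list was 0.06, its mean -0.14 and its test pointed up. YAP and TEAD targets had 6 of 20 higher and 2 lower (TGFB2 and WWTR1), and MAP kinase feedback genes 8 of 19 higher and 1 lower (DUSP4), each the same adjusted over the list alone, and EREG, of the growth factor epiregulin, rose by 2.78 (SE 0.36). Fry called the MAP kinase list higher (adjusted p = 0.0216). Growth factor receptors had 3 of 11 lower (FGFR1, MET and FLT1) and 1 higher (EPHA2), with 5 and 1 adjusted over the list alone, the call of FGFR1 being lost without untreated replicate 2 (adjusted p = 0.0711), OMX replicate 2 (0.0906) or OMX replicate 3 (0.0652).

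Among 14 interferon-response genes measured in Gracie ISG20, an exonuclease gene, was higher, going from 6 to 519 counts (log2 fold change 6.17, SE 0.62, or 10.36 without untreated replicate 2, which held all 6, so that this is no bound), and the others were not called, the same adjusted over the list alone. The list's median was -0.16, its mean 0.23, and its test pointed down while fry pointed up. RNA polymerase I genes had 2 of 33 higher (TAF1C and NOB1) and 2 lower (UBTF and DKC1), with 2 and 1 adjusted over the list alone. Factors of mRNA decay had 5 of 21 higher (ZC3H12A, XRN1, RC3H2, CNOT3 and EXOSC10) and 2 lower (PAN2 and CNOT6), SR proteins and splicing factors 3 of 24 higher (RBM5, CLK3 and RBM39), nonsense-mediated decay factors 2 of 10 higher (SMG6 and UPF2), and caspases, their inhibitors and death receptors 2 of 15 higher (BIRC3 and CFLAR), each the same adjusted over the list alone. UPF2 lost its call without untreated replicate 2 (adjusted p = 0.0532) or OMX replicate 2 (0.0617). Of 5 Wnt and Notch targets measured, edgeR called 0, over all genes and adjusted over the list alone, and 0 had an unadjusted p under 0.05. JAG1, of a Notch ligand, had a log2 fold change of 0.99 (SE 0.69, adjusted p = 0.335 by edgeR) and NOTCH1 -0.47 (SE 0.36, adjusted p = 0.381 by edgeR). No marker of another cell type was called in Gracie over all genes, and CTSK, a protease gene of osteoclasts, was lower adjusted over the list alone (-0.62, SE 0.27, adjusted p = 0.122 over all genes).

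**Figure D3:**
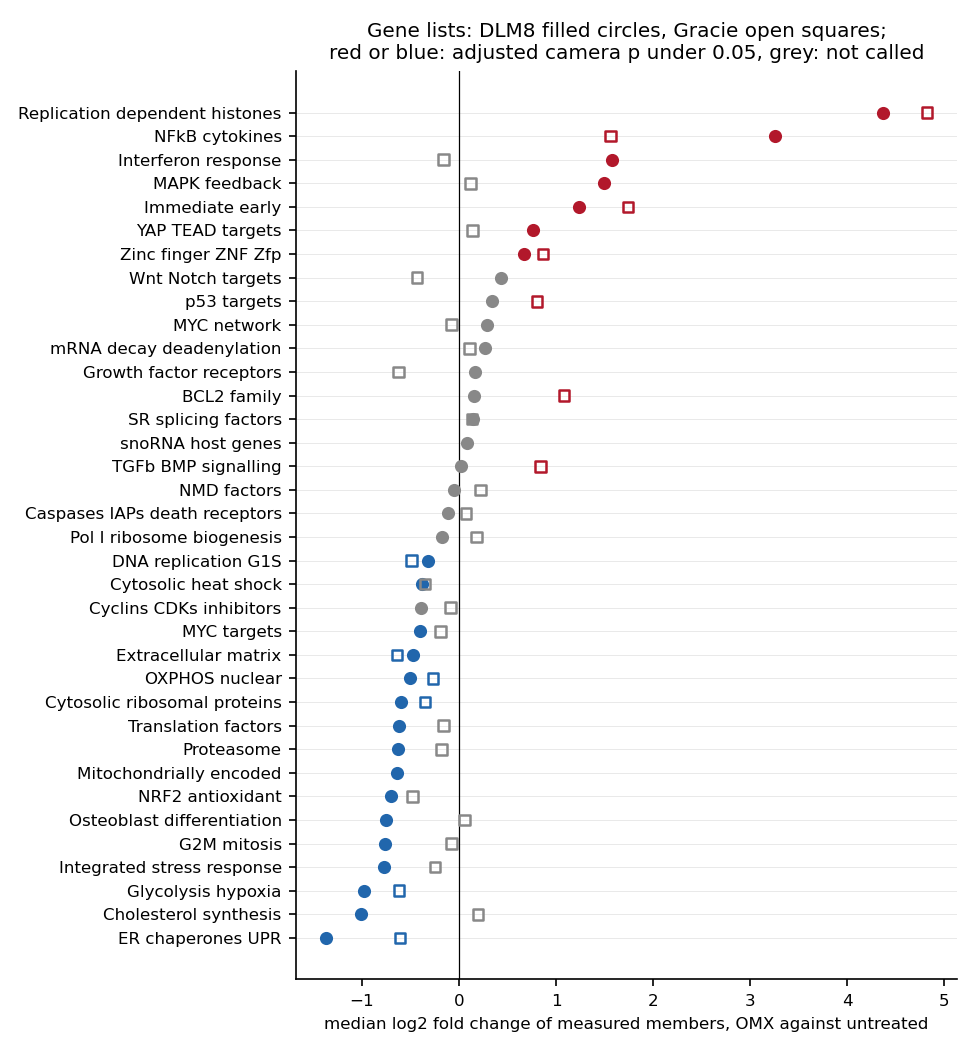
Median log2 fold change (OMX against untreated) of the members of each tested gene list, DLM8 as filled circles and Gracie as open squares. Red and blue mark lists called higher and lower by camera with its preset correlation and grey lists not called: 7 higher and 16 lower of 36 in DLM8, and 7 and 6 of 34 in Gracie.

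The last comparison asked whether the genes that responded in 1 line responded in the other. GADD45B rose in both, by 5.81 (SE 0.21) in DLM8 and 5.29 (SE 0.22) in Gracie, and the difference was not called (0.51, SE 0.30, adjusted p = 0.298). Csf2 had 0 untreated counts in both lines and was at least 25.0-fold higher in DLM8 and at least 23.1-fold higher in Gracie. NEURL3, EGR1 and TXNIP, an inhibitor gene of thioredoxin, were also among the largest shared rises, with a TXNIP rise of 4.23 (SE 0.22) in DLM8, where its facing row Gm15441 held 46.4 times its counts and rose by 4.61 (SE 0.23), and of 6.55 (SE 0.53) in Gracie. Shared falls were led by STC1, which encodes the hormone stanniocalcin, LGR4, ANGPTL2, SLC2A1 and PON2. SLC2A1 fell by 2.92 (SE 0.38) in DLM8 and 2.28 (SE 0.24) in Gracie. Stc1 went from 109 to 2 counts in DLM8, a ratio of 0.0172 (95% interval 0.00206 to 0.0638, or 0.000428 to 0.1 with halved counts), and fell by 1.02 (SE 0.19) in Gracie. The DLM8 call of Lgr4 (adjusted p = 0.0485) was lost without untreated replicate 2 (0.142) or 3 (0.169), without OMX replicate 1 (0.0942) or 3 (0.141), and with library size alone (0.0678). PON2 lost its Gracie call without untreated replicate 1 (adjusted p = 0.105), OMX replicate 1 (0.0597), 2 (0.0627) or 3 (0.0733). Beside EGR1, 4 of the 10 shared genes differed in the size of their response by the interaction in edgeR (DLM8 minus Gracie, log2). These were TXNIP (-2.34, SE 0.59, adjusted p = 0.0137), ANGPTL2 (1.83, SE 0.41, adjusted p = 0.00602), STC1 (-4.49, SE 0.70, adjusted p = 0.000284, from 2 DLM8 counts with OMX, so that its size depends on the prior count) and LGR4 (2.93, SE 0.89, adjusted p = 0.0373). The LGR4 difference lost its call without DLM8 untreated replicate 1 or 2 or OMX replicate 2 and without Gracie untreated replicate 2 or 3 or OMX replicate 1 or 2 (adjusted p from 0.0550 to 0.161).

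Over 7566 genes with the same symbol in both tables, the log2 fold changes of both lines correlated with Pearson r = 0.404 (jackknife SE 0.0230) and Spearman rho = 0.384, across genes, which are not independent replicates. Of 666 genes called in both lines 308 were higher in both and 282 lower in both, where independent lists would share 113 and 113, and 76 were called in opposite directions, where 234 would be, so 88.6% had the same direction. The count lower in both was 169 without Gracie untreated replicate 2, 134 without Gracie OMX replicate 2 and 180 without Gracie OMX replicate 3, and the opposite count was 44, 34 and 49 in turn and 49 without DLM8 OMX replicate 2. Among immediate early genes, 18 of 36 measured in both lines were higher in both.

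**Figure D4:**
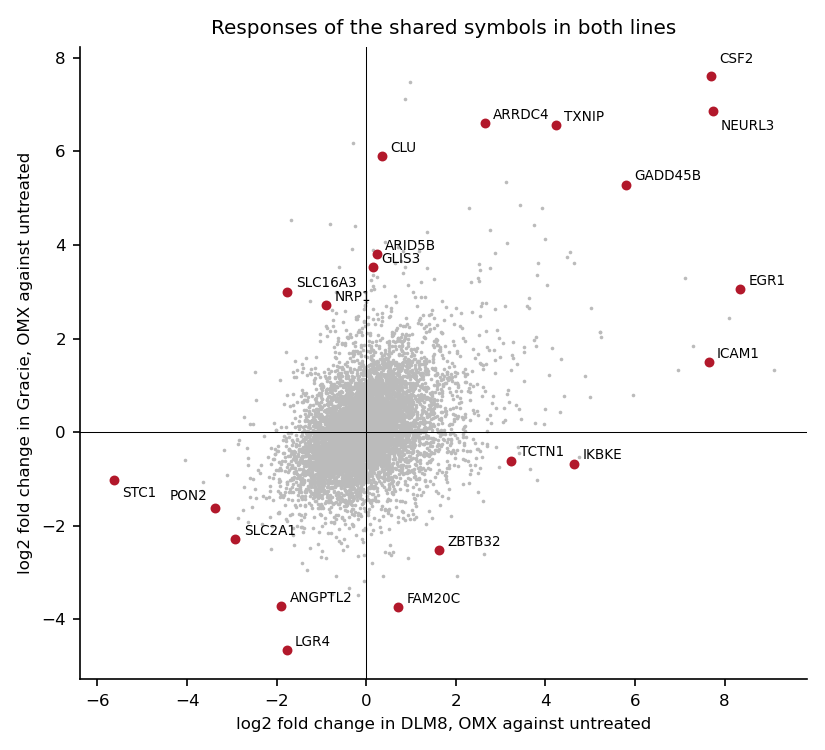
Log2 fold changes (OMX against untreated) of 7566 genes with the same symbol, DLM8 on the x axis and Gracie on the y axis, each point a gene and the genes named in the comparison of the lines in red. The cloud tilts upward with Pearson r = 0.404.

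The responses themselves were compared with an interaction of line and treatment in edgeR. ICAM1 rose more in DLM8 (7.65, SE 0.35) than in Gracie (2.83-fold, with an SE of 0.32 on the log2 scale), and IKBKE, of an NF-kB pathway kinase, rose by 4.64 (SE 0.38) in DLM8 while its Gracie value was -0.67 (SE 0.34, adjusted p = 0.178). The row facing Ikbke, Gm28913, held 9.90 times its counts and rose by 0.65 (SE 0.18). The row facing Icam1, Gm47079, held 20.3 times its counts and rose by 5.53 (SE 0.27). EGR1 rose by 8.34 in DLM8 and 3.05 (SE 0.44) in Gracie, and ZBTB32, a transcription repressor gene, rose by 1.62 (SE 0.26) in DLM8 and fell by 2.53 (SE 0.35) in Gracie. The lactate transporter gene SLC16A3 fell by 1.76 (SE 0.18) in DLM8 and rose by 3.00 (SE 0.39) in Gracie, and clusterin (CLU) rose by 5.90 (SE 0.81) in Gracie, from 8 to 575 counts, against 0.35 (SE 0.22, adjusted p = 0.238) in DLM8. All 8 untreated Gracie counts of CLU were in replicate 1, and without it the fitted value was 10.49 against untreated counts of 0, which is no bound. NRP1, a coreceptor gene for semaphorins, rose by 2.71 (SE 0.31) in Gracie, and its lower DLM8 value (-0.89, SE 0.31) lost its call without any 1 library but OMX replicate 2 (adjusted p from 0.0630 to 0.101) and with library size alone (0.0803). In all, 445 genes had a higher response in DLM8 and 469 a lower one at an adjusted p under 0.05, and 1965 had an unadjusted p under 0.05. With library size alone these were 653 and 241. By camera, 7 of 33 lists differed between the lines, and none held with an estimated correlation (adjusted p from 0.243 to 0.468).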

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

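The tests of mt-Nd6, of the rank of all 78 ribosomal protein rows and of an even background were chosen only after the result was seen, and the others in this part, the rank of ribosomal protein genes facing no gene included, before.

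The responses of the lines differed by a test of the interaction itself in 914 genes, 445 with a higher and 469 with a lower response in DLM8. Of 100 splits of the libraries within lines, 1 (the real one) gave as many, with 464 in the highest of the others and a median of 0. Regrouping also removes the OMX response of each line and adds it to the spread, so these splits do not test an equal response in both lines, and chance is left open by them. With library size alone the split was 653 and 241, so the balance of both directions rests on the scaling.

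Among the largest positive differences (DLM8 minus Gracie, log2), ICAM1 differed by 6.13 (SE 0.54, adjusted p = 3.29e-06) and EGR1 by 5.26 (SE 0.78, adjusted p = 0.00019), each a rise in both lines of another size. IKBKE differed by 5.30 (SE 0.52, adjusted p = 4.12e-06) and TCTN1 by 3.85 (SE 0.50, adjusted p = 6.65e-05), both called in DLM8 and not in Gracie. Gm28913, the row facing Ikbke in DLM8, held 9.90 times its counts and rose by 0.65, and Tctn1 rose by 3.24 in DLM8, where it faces Hvcn1 (2.01). Gm47079, the row facing Icam1, held 20.3 times its counts and rose by 5.53, less than the Icam1 row (7.65). The IKBKE and TCTN1 differences and the size of the ICAM1 difference are therefore uncertain. Dog gene positions were not used, so a difference in facing genes between the species was not told apart from a difference in response. FAM20C differed by 4.47 (SE 0.46, adjusted p = 5.5e-06), with 0.72 in DLM8 against -3.74 in Gracie, and ZBTB32 by 4.15 (SE 0.46, adjusted p = 1.4e-05).

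Among the largest negative differences, CLU differed by -5.58 (SE 0.85, adjusted p = 0.000264), or by -11.36 without Gracie untreated replicate 1, which held its 8 untreated counts, and SLC16A3, the lactate transporter gene, by -4.76 (SE 0.47, adjusted p = 4.12e-06). ARRDC4 differed by -4.08 (SE 0.86, adjusted p = 0.00386), or by -7.93 without Gracie untreated replicate 1, with 2 untreated counts in Gracie, so the size of this difference depends on the prior count. NRP1 differed by -3.60 (SE 0.45, adjusted p = 4.76e-05). ARID5B differed by -3.58 (SE 0.54, adjusted p = 0.000205) and GLIS3 by -3.38 (SE 0.50, adjusted p = 0.000169), with rises of 3.80 and 3.53 in Gracie and values of 0.24 and 0.16 in DLM8 that were not called. Of genes that moved the same way in both lines, TXNIP differed by -2.34, STC1 by -4.49, ANGPTL2 by 1.83 and LGR4 by 2.93, the last losing its call without 7 of the 12 libraries (adjusted p from 0.0550 to 0.161).

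Of 33 lists, 7 differed between the lines by camera with its preset correlation, and 0 of these with an estimated one. The median difference was 0.75 for NF-kB and cytokine genes (adjusted p = 0.00561, and 0.243 with an estimated correlation). For chaperone and unfolded protein response genes of the endoplasmic reticulum it was -0.89 (0.0159 and 0.243). It was -0.60 for mitosis (0.0086 and 0.319) and -1.19 for cholesterol synthesis (0.000216 and 0.243). It was 0.72 for YAP and TEAD targets (0.0086 and 0.319), 0.39 for MAP kinase feedback (0.0264 and 0.319) and 1.51 for 9 interferon-response genes (0.0325 and 0.468).

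In DLM8 rows that face abundant mRNAs held more counts than the rows of those mRNAs. Unstranded counting is argued against by the ribosomal protein genes that face no gene, of which 5% (3 of 60) were among the 1000 rows with the most counts, where full counts would put most of them. Antisense RNA made at these loci is argued against by the 4 of 78 ribosomal protein rows in that set, since it would leave their own mRNAs counted. Both arguments are limited, because the rule for reads with several positions is not given. Dropping such reads could lower ribosomal protein rows under any strand setting, and this was not tested. Counting on the opposite strand needs a high mt-Nd6 row, and this row held at least 49.9 times the median of the other mitochondrial protein rows in each library. A candidate explanation is therefore a strand-specific kit, as this one is known to be, counted with the opposite setting, which the labels do not state, and the dog table was not tested.

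More genes had counts in OMX libraries (24159 to 26417 against 21790 to 22179 in DLM8, and 13702 to 14235 against 12265 to 12609 in Gracie), and more genes were over 2-fold higher than lower. Depth is argued against in both lines, since after thinning all libraries to the smallest total of their line the lowest OMX library still held 2115 more genes than the highest untreated one in DLM8 and 1055 more in Gracie. In DLM8 2181 silent rows held 0.0189 to 0.0240 CPM per kb in untreated libraries and 0.0296 to 0.0388 with OMX, a mean gain of 0.0143. An even background of reads with this gain could account for 0.0574% of 1741 genes over 2-fold higher with an exon length, even at 3 times the gain. For 643 such genes without an exon length the share was 38.6% at the longest exon length of any gene, so there it stays open, and in Gracie it was not tested. An effect of OMX on transcription or RNA decay stays open and untested.

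For the gene counts of a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 6037 calls in DLM8 against 0 in the highest other, 1 split reaching as many, and 2148 in Gracie against 1, again 1 split. For lists the real split gave 23 in DLM8 against 17 in the highest other and a median of 13 over the others (1 split as large), and 13 in Gracie against 15 and a median of 6 (2 splits as large). Every other split mixes both treatments unevenly, so a part of the OMX response stays in the comparison and the rest adds to the spread. The other splits thus do not show what either count would be without a response, and chance is left open by them. A single list call with the preset correlation stays weak evidence, since in each line 1 called list held with an estimated correlation.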

How the results depend on the processing

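Settings added after seeing the data were the halved counts, Gracie without its 2 genes with the most counts, and genes facing no annotated gene in DLM8. No called gene or list changed direction under any setting run for it. Named genes kept both their direction and their side of the threshold in 875 of 884 values under other settings (3 weaker and 6 stronger) and in 1273 of 1324 values with 1 library left out (47 weaker, 3 stronger and 1 turned). Lists did so in 326 of 384 (42 weaker, 7 stronger and 9 turned) and 370 of 420 (24, 9 and 17), and interactions of named genes in all 105 and in 244 of 252 (7 weaker, all of LGR4, and 1 turned). The Myc rise of DLM8 stayed called (log2 fold change 1.09 to 1.42, adjusted p from 1.53e-08 to 0.00227) and that of Gracie uncalled (0.26 to 0.70, adjusted p from 0.0557 to 0.582).

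Lists not called, before or after, turned in the direction of their test, with these medians. In DLM8 the MYC network (median 0.29) turned under fry, with library size alone (0.44) and without untreated replicate 1 or 2 or OMX replicate 1 (0.045 to 0.52 over the left-out libraries). Caspases (-0.11) turned with the replicate block, with library size alone (0.029) and without untreated replicate 1 or OMX replicate 2 (-0.31 to 0.14). Wnt and Notch targets (0.44) turned under fry and without untreated replicate 2 or 3 (0.11 to 0.49), splicing factors (0.033 to 0.18) and growth factor receptors (-0.19 to 0.25) without OMX replicate 1, and nonsense-mediated decay (-0.047) among genes facing none. In Gracie interferon genes (-0.16) turned under fry, osteoblast genes (0.056) with the replicate block, and RNA polymerase I genes with library size alone (0.064) and without untreated replicate 1 or OMX replicate 3 (0.035 to 0.24). The MYC network turned without untreated replicate 2 or 3 or OMX replicate 1 (-0.17 to 0.026), and cholesterol synthesis without untreated replicate 3 or OMX replicate 1 or 2 (-0.065 to 0.35). Glis3 of DLM8, not called, had -0.016 without OMX replicate 3 (-0.016 to 0.36), and the NEURL3 interaction, not called, turned without Gracie untreated replicate 3 (-3.13 to 1.41), and the cause of these turns was not tested.

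Of the 6037 calls in DLM8, 6004 were also made by DESeq2 and 5791 by limma-voom in the same direction, and of 2148 in Gracie 2132 and 2041. Among genes facing no annotated gene DLM8 had 1107 higher and 1242 lower (911 and 711 over 2-fold), with fewer genes tested by construction. With an estimated correlation 1 list was called higher and 0 lower in each line, and fry called 2 lower in Gracie. For some lost lists the estimate lay below the preset correlation, so a higher one does not account for every loss. The cause was not tested. Library size alone gave 241 interactions with a lower response in DLM8, as the scaling factor moves all fold changes of a line together. Genes with a mean log2 CPM of at least 3 in both lines had Pearson r = 0.487.

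With 1 Gracie library left out, Gracie had 827 to 1462 genes higher and 395 to 925 lower (358 to 565 over 2-fold lower), from fewer samples. The lowest values came without OMX replicate 2, and the lower count was 495 without untreated replicate 2 and 553 without OMX replicate 3. With 1 library of either line left out, Pearson r was 0.369 to 0.397, genes lower in both lines 134 to 327, and genes called in opposite directions 34 to 104.

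The replicate number as a block gave 3629 higher and 3217 lower in DLM8 and 1427 and 1010 in Gracie, and 509 and 615 interactions. It ended the p53 list's call in Gracie (adjusted p = 0.0588) and the call of Lgr4 in DLM8 (0.0609). Residuals of libraries with the same number correlated at 0.20, 0.04 and 0.11 in DLM8 and 0.13, -0.02 and 0.18 in Gracie. Those of libraries with different numbers lay from -0.164 to 0.062 in DLM8 and from -0.173 to 0.032 in Gracie. Whether the numbers pair the libraries is thus left open.

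At this depth and spread the simulated recovery was 15% of 2-fold and 83% of 4-fold changes in Gracie, and 45% and 78% in DLM8. The simulation changed a far smaller share of genes than was called in the data (35.3% in DLM8 and 20.6% in Gracie). With fewer changed genes the Benjamini-Hochberg adjustment is stricter, so these values may understate the recovery in the data, which was not measured. A gene not called is still not shown to be unchanged. Depth and the spread between libraries were not told apart by the simulation.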

Other observations

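The scaling test and the motif test limited to genes facing no annotated gene were chosen only after the result was seen, and the motif test on all genes before.

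ATF4, SP7, EIF3G and ISG20 responded differently in the lines by the interaction in edgeR. They were picked here after their values were seen, with no alternative settings run for the differences, and do not stand for a list. ATF4 rose by 1.84 (SE 0.20) in Gracie and had 0.11 (SE 0.16) in DLM8, a difference of -1.73 (SE 0.28, adjusted p = 0.000436). SP7, the osterix gene, rose by 2.35 (SE 0.35) in Gracie against -0.52 (SE 0.21) in DLM8, where it was not called, a difference of -2.88 (SE 0.37, adjusted p = 5.61e-05). EIF3G rose by 2.01 (SE 0.21) in Gracie and fell by 0.63 (SE 0.19) in DLM8, a difference of -2.64 (SE 0.30, adjusted p = 1.49e-05). ISG20 rose in Gracie and had -0.29 (SE 0.42) in DLM8, a difference of -6.51 (SE 0.75, adjusted p = 1.89e-05). Its Gracie value went from 6.17 to 10.36 without untreated replicate 2, which held all its untreated counts, so the size of this difference rests on that library.

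In DLM8 the inhibitor of apoptosis gene Birc3 rose by 4.54 (SE 0.66, or 6.93 without untreated replicate 2, which held 15 of its 17 untreated counts) and the death receptor gene Fas by 3.98 (SE 0.66), while Bak1, a pro-apoptotic BCL2 family gene, fell by 1.07 (SE 0.19). The antiproliferative gene Btg2 rose by 2.85 (SE 0.40) and Cdk1, the mitotic kinase gene, fell by 1.84 (SE 0.31). Skil, a repressor gene of TGF-beta signalling, rose by 3.06 (SE 0.33) and Bambi, a pseudoreceptor gene of that family, fell by 1.74 (SE 0.29). In Gracie CFLAR, an inhibitor gene of caspase activation, rose by 1.94 (SE 0.43), the peroxiredoxin gene PRDX1 fell by 1.70 (SE 0.28) and PAN2, of a deadenylase, fell by 1.65 (SE 0.21).

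Of immediate early genes 28 of 42 were higher in DLM8 and 24 of 37 in Gracie, and of NF-kB and cytokine genes 29 of 31 and 17 of 28, with TNF lower in Gracie, and Myc was higher in DLM8. With an estimated correlation the list calls were lost for immediate early genes (adjusted p = 0.142 in DLM8 and 0.144 in Gracie) and for NF-kB in Gracie (0.171), and held for NF-kB in DLM8 (0.0162). The lowest median of the immediate early list over both lines and RLE, upper-quartile and library-size scaling was 1.17, so the choice among these scalings does not account for the rise. They moved the median gene by at most 0.14 from TMM, so this test could hardly have come out otherwise. A scaling error common to all of them stays open. A hypothesis is that mRNAs with AU-rich elements decay more slowly when translation is blocked. In DLM8, genes with TATTTAT in a 3' UTR had a log2 fold change higher by 0.11 (SE 0.026) at equal UTR length, AT content and level over 10921 genes, rank 1 of 21 motifs with the same bases (next TTATTAT, 0.10, SE 0.031), but among 7072 genes facing no annotated gene it was 0.083 (SE 0.033) and rank 3. The motif was in 25 of 42 immediate early genes (59.5%) against 30.1% of all, but its effect is far smaller than the list's median of 1.23, so it may add to that rise and is not shown to account for it, and an effect of OMX on transcription stays open and untested.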
